A study of Carassius carassius with 6 samples.

How the data were processed

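Brain RNA was measured by RNA sequencing in 6 libraries of juvenile crucian carp (Carassius carassius), 3 from an unexposed control group and 3 from fish exposed to deltamethrin at 0.6 µg/L for 28 days. Groups and replicate numbers were taken from the sample titles, and each column of the expression table carried the name that a sample's description gives. Whether a library came from 1 fish or from several is not given in the sources used here, so the p-values measure the spread between these libraries, which may be in part technical. Per the labels' protocols, total RNA was extracted with TRIzol, checked on a Bioanalyzer and made into libraries with a VAHTS Universal V6 RNA-seq kit. CASAVA is the program named in the submitters' processing notes. The aligner, the counting program, the genome build, the gene annotation and the strand setting are not given in the sources used here.

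The authors deposited 1 table of FPKM values (fragments per kilobase of gene per 1000000 counted fragments) for 41199 genes, with 1 column per library and no filter on low values visible. Its genes carry Ensembl-style identifiers, and the file does not pair them with names. The gene table of the reference assembly fCarCar2.1 of the species on the labels holds 70659 genes, of which 0 have an Ensembl identifier, and 0 of the 41199 identifiers were found in it. The 41 lists of pathways and cell type markers that had been fixed before the data were examined therefore could not be applied with the sources used here. No gene list was tested. No gene name, position or function is given for the same reason, and at most 2 identifiers per direction are printed.

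The depth was recovered from the deposited FPKM values. Low values of a gene were whole multiples of a fixed step in each library. From these steps the total of each library was found as the common divisor of the products of gene length and library total over 17102 genes, and the count and length of every gene followed as the smallest whole numbers that gave its FPKM values. All 25688 tested genes (100.0%) gave whole fragments in all 6 libraries within 0.001 of a whole number. A common factor of all counts and the length of a gene cannot be recovered, so a count and a length can be too low by such a factor. Summed over the listed genes, the recovered fragments made up 99.6% of each library total. In simulated FPKM values the method recovered all 6 library totals, and every count of 99.1% of 25714 genes. The recovered totals ran from 20284797 to 22279901 fragments per library, with a median of 329 fragments per tested gene and library. The fragments carry no molecular identifiers.

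The main test, chosen before the data were examined, was limma (version 3.58.1, R 4.3.3) on log2(FPKM + 1), with an abundance trend in the variance prior, group as the single factor, two-sided p-values and Benjamini-Hochberg adjustment at 0.05. It covered the 25688 genes with a mean FPKM of at least 1 over the 6 libraries. A fold change is thus on the log2(FPKM + 1) scale, which understates the change of low genes. Intervals are moderated 95% confidence intervals. The rule for single genes was fixed in advance only in part. It took genes past the threshold by fold, and, where too few passed, the smallest unadjusted p in each direction. As planned, it covered more genes per direction and only genes with a name. With no names paired to the identifiers, it was cut to 2 unnamed identifiers per direction after the data were examined. Library distances were described by Pearson correlations across genes and principal components of the same values.

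The test was run on simulated counts drawn for the 25688 genes at their observed means, library totals and spread within groups, with 200 genes changed, in 3 draws. It called 66.2% of the genes changed 4-fold, 28.4% of those changed 2-fold and 3.48% of those changed 1.5-fold, with 9 false calls over the 3 draws. With 2000 genes changed 2-fold, in 1 draw, it called 65.5% of them. Genes were drawn independently, and the spread estimated for each gene from 3 libraries per group was taken as its true spread. The real libraries share structure across genes, so these shares are a rough guide to the power of the real test.

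The alternatives were pseudocounts of 0.1 and 0.01, no filter on low values, a minimum mean FPKM of 5, median-of-ratios scaling, quantile normalization, the replicate number as a block, the variance prior without a trend, a robust prior, estimated library weights, other thresholds, and each library left out in turn. Chosen after seeing the data were limma's voom on the recovered fragments with the recovered library totals, removal of a lowess trend with log2 gene length (span 0.3) from each library, that removal with the block, and the joint removal of 2 libraries that stood apart. Python 3.11.15 with scipy 1.17.1 was used for the rest.

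Control and exposed libraries share the numbers 1 to 3, with no statement that a number marks a shared tank or day. The numbers were therefore not taken as pairs. The deviations of same-numbered libraries from their group means correlated at 0.01, -0.18 and 0.23, which cannot exclude pairing with 3 libraries per group. The labels give no sequencing batch or date. No 2 libraries agreed within sampling noise: over genes, the chi-square per degree of freedom of a pair was at least 15.2, where sampling noise alone gives about 1.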

Results

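The study asked how the brain transcriptome of juvenile crucian carp differs after long exposure to deltamethrin, a pyrethroid insecticide that acts on voltage-gated sodium channels of nerve cells. Expression per gene was measured by RNA sequencing in 3 control libraries and 3 libraries from fish kept for 28 days in water with 0.6 µg/L deltamethrin. The recovered library totals were 21019580, 21504913 and 20284797 fragments in control replicates 1, 2 and 3, and 20834735, 22279901 and 21393996 in deltamethrin replicates 1, 2 and 3. Between 34211 genes (control replicate 2) and 35178 genes (deltamethrin replicate 2) were above 0 in a library, out of 41199 listed. The 50 most abundant genes held between 7.73% and 8.60% of the listed fragments of a library.

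No gene differed between deltamethrin and control brains at the adjusted threshold. Of 25688 genes tested with limma, 0 had an adjusted p under 0.05, and the smallest adjusted p was 0.627. At an unadjusted p under 0.05 there were 1103 genes, 616 higher and 487 lower in the exposed group, where 5% of the genes tested would be 1284. The balance of directions turned with the scaling, to 542 higher and 586 lower under median-of-ratios scaling and 532 higher and 576 lower under quantile normalization. A second test, limma's voom on the recovered fragment counts, also gave 0 genes at the adjusted threshold and 997 at the unadjusted one. The unadjusted p-values were spread almost evenly, with 1103 genes between 0 and 0.05 and between 1219 and 1389 in each other step of 0.05. Limma's convest estimate of the share of unchanged genes was 1, and its lfdr estimate was 0.998. Both estimates assume evenly spread p-values for unchanged genes. Other splits of the 6 libraries into 3 and 3 gave 534 to 2291 genes at an unadjusted p under 0.05 (limma). The estimates therefore do not show that no gene changed. All 3 exposed values lay above all 3 control values in 1463 genes and below them in 1155 genes, together 10.2% of the genes, where chance gives 10%.

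**Figure D1:**
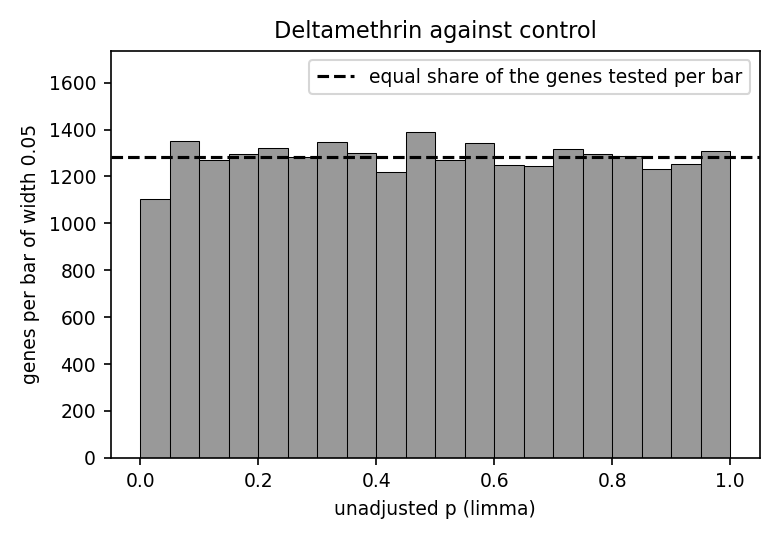
Number of genes (y axis) by unadjusted limma p-value for deltamethrin against control (x axis, 20 bars of width 0.05) over 25688 genes; the dashed line is an equal share per bar. The lowest bar holds 1103 genes, fewer than any other bar.

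Differences of more than 2-fold on the log2(FPKM + 1) scale were bounded for most genes. The median absolute log2 fold change was 0.12, and 95% of the genes lay under 0.44. The median standard error was 0.17, and the 95% interval reached a median of 0.38 to either side. For 23963 genes (93.3%) the 95% interval lay within a 2-fold change in either direction, and for 62.6% it lay within a 1.5-fold change. These are intervals for single genes, without correction for their number, on the log2(FPKM + 1) scale. On that scale a 2-fold bound allows a larger change in the FPKM of low genes. Among genes with a mean FPKM of 1 to 5, 88.0% of the intervals lay within the 2-fold bound. An unadjusted p under 0.05 together with at least a 2-fold change was met by 72 genes, 55 higher and 17 lower. Without control replicate 2 it was met by 44 higher and 48 lower genes. Higher genes outnumbered lower ones under every other setting run, as with the length trend removed (63 higher, 9 lower). The count of 72 rose to 163 without deltamethrin replicate 3, to 110 without deltamethrin replicate 1 and to 180 with a pseudocount of 0.01. Other splits of the same 6 libraries into 3 and 3 gave between 30 and 113 such genes.

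The genes were also grouped by abundance. Among 9617 genes with a mean FPKM of 1 to 5, 238 were higher and 145 lower at an unadjusted p under 0.05, with a median standard error of 0.20. The 10516 genes with a mean of 5 to 20 FPKM included 267 higher and 209 lower at that level, with a median standard error of 0.15. Of the 4622 genes between 20 and 100 FPKM, 101 were higher and 107 lower, with a median standard error of 0.13. In the 933 genes at 100 FPKM or more, 10 were higher and 26 lower. The share at an unadjusted p under 0.05 was 3.98%, 4.53%, 4.50% and 3.86% from the lowest class to the highest, under 5% in each. No class held a gene past the adjusted threshold, the smallest adjusted p (limma) being 0.868, 0.627, 0.839 and 0.868. The adjustment ran over all tested genes together, so this follows from the main result and is no separate test per class.

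The genes with the smallest unadjusted p in each direction had values that did not overlap between groups but did not pass the test. ENSCARG00000021564 was at 6.51 ± 1.61 FPKM in control (SD, n = 3) and 19.4 ± 1.68 FPKM in deltamethrin (SD, n = 3), a ratio of means of 2.97. Its log2 fold change was 1.46 with a standard error of 0.18 and an adjusted p of 0.627 (limma), on 21 to 103 recovered fragments per library. ENSCARG00000017770 was at 3.24 ± 0.62 FPKM in control and 9.01 ± 1.12 FPKM in deltamethrin (SD, n = 3 each), with a log2 fold change of 1.24, a standard error of 0.16 and an adjusted p of 0.627 (limma). In the other direction, ENSCARG00000033978 was at 10.3 ± 1.05 FPKM in control and 4.85 ± 0.88 FPKM in deltamethrin (SD, n = 3 each). Its log2 fold change was -0.95 with a standard error of 0.15 and an adjusted p of 0.839 (limma). ENSCARG00000008809 was at 11.03 ± 1.96 FPKM in control and 3.21 ± 1.90 FPKM in deltamethrin (SD, n = 3 each). Its log2 fold change was -1.59 with a standard error of 0.29 and an adjusted p of 0.868 (limma). These 4 genes ranked 1, 2, 7 and 14 among the 25688 genes by unadjusted p. What they encode was not analysed here, since no source used here pairs the identifiers with names.

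**Figure D2:**
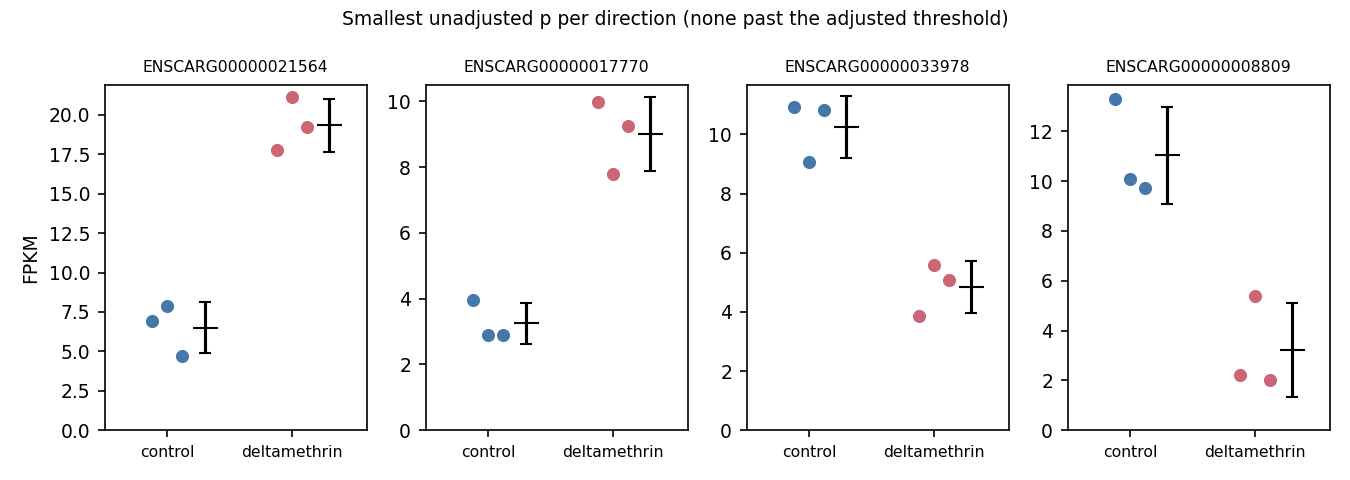
FPKM (y axes, from 0) of the 4 genes with the smallest unadjusted p per direction in each control and deltamethrin library; points are libraries, and the black bar is the mean with its SD (n = 3). The groups do not overlap in any of the 4 genes, and none passed the adjusted threshold.

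The libraries did not separate by group. The Pearson correlation across genes was 0.968 on average both for pairs within a group (range 0.960 to 0.976) and for pairs between groups (range 0.957 to 0.978). The mean within groups minus the mean between groups was -0.000575. Among the 10 splits of the libraries into 3 and 3, 6 gave a difference at least as large in favour of within-group pairs (exact permutation test, one-sided p = 0.6, and 0.1 is the smallest p that 10 splits allow). The closest pair was control replicate 3 with deltamethrin replicate 3, and the most distant pair was control replicate 3 with deltamethrin replicate 1. The first principal component held 31.1% of the variance, with deltamethrin replicate 1 (38.8) and control replicate 2 (25.2) at its upper end and control replicate 3 (-27.6) at its lower end. The second held 25.5% and set deltamethrin replicate 2 (41.9) apart from the other 5 libraries, which lay between -22.7 and 11.3.

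**Figure D3:**
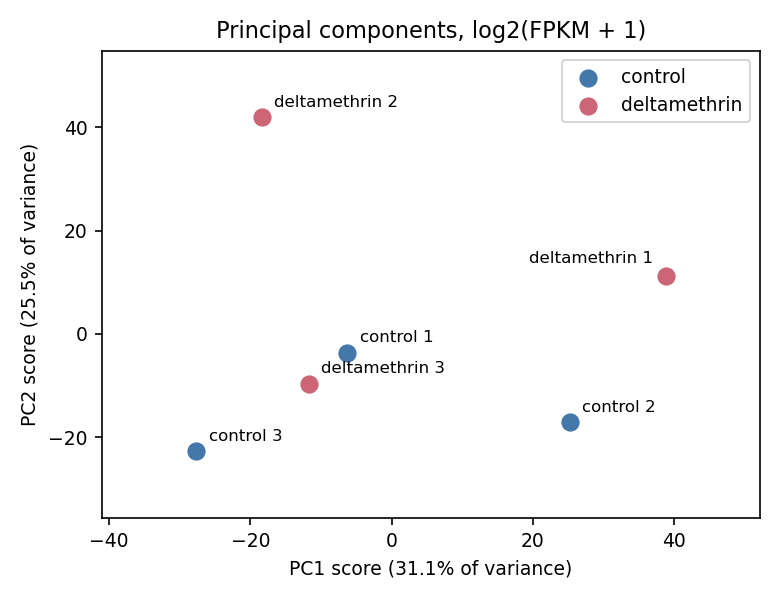
Scores of the 6 libraries on the first (x axis, 31.1% of variance) and second (y axis, 25.5%) principal components of log2(FPKM + 1) over the tested genes; each point is a library, coloured by group. Control and deltamethrin libraries are interleaved on the first component, and deltamethrin replicate 2 is highest on the second.

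Libraries stood apart from the rest in both groups. In deltamethrin replicate 2, 100 genes were at 2 FPKM or more and at least 8-fold above every other library, against 1 to 7 genes in the other libraries. Their median was 6.17 FPKM in that library, on a median of 148.5 fragments, and the median of their highest value elsewhere was 0.292 FPKM. Together they held 0.115% of the fragments of that library. In control replicate 3, levels fell with gene length: the median log2 deviation from the mean of the 6 libraries was 0.11 in the shortest 20% of genes and -0.11 in the longest 20%. The Spearman correlation of that deviation with length across genes, which are not independent replicates, was -0.28 in control replicate 3 and between -0.04 and 0.17 in the other libraries. Without deltamethrin replicate 2 and control replicate 3 together, which left 2 libraries per group, limma gave 0 genes at the adjusted threshold and 828 at an unadjusted p under 0.05. The smallest adjusted p of that fit was 0.0685 (limma), close to the threshold. This pair was chosen after seeing the data, and no other pair was left out. Deltamethrin replicate 1 also stood apart, at the upper end of the first principal component.

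**Figure D4:**
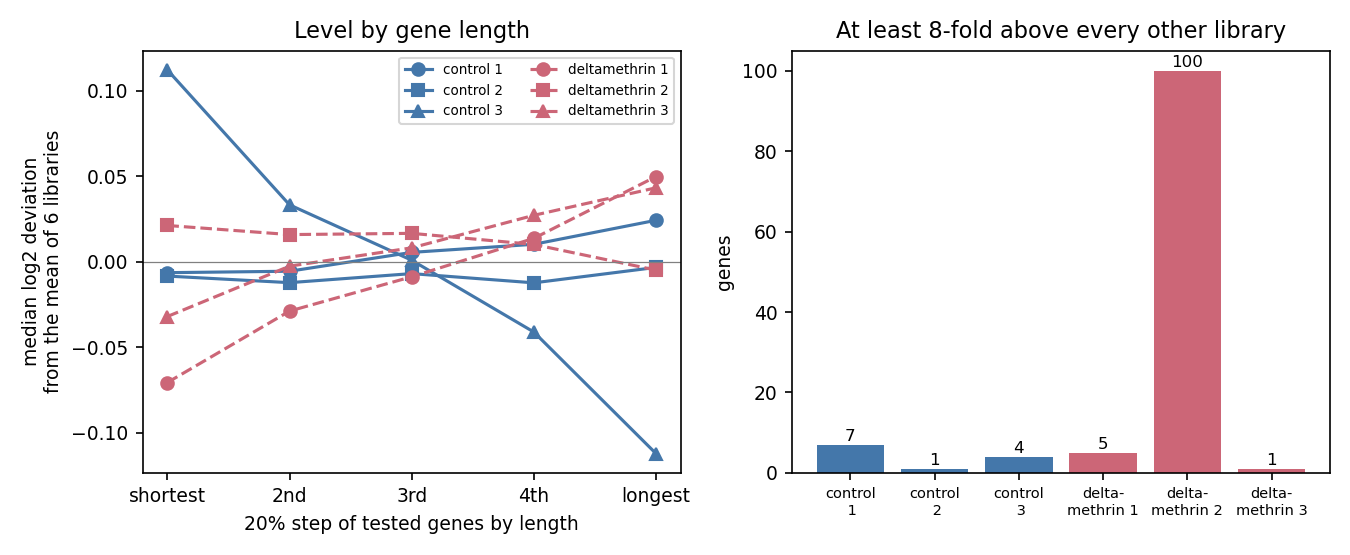
Left, median log2 deviation from the mean of the 6 libraries (y axis) by 20% steps of tested genes by length (x axis), 1 line per library (solid, control; dashed, deltamethrin). Right, number of genes at 2 FPKM or more and at least 8-fold above every other library. Control replicate 3 falls from 0.11 to -0.11, and deltamethrin replicate 2 has 100 such genes.

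The count of 0 depended on which exposed library was included. Without deltamethrin replicate 2, 1 gene passed the adjusted threshold (adjusted p = 0.0153, limma), and without deltamethrin replicate 3, 4 other genes did, with a smallest adjusted p of 0.00271; all 5 were higher in deltamethrin and each had an adjusted p of 0.994 with all 6 libraries. The 1 gene was at 18.4 and 20.5 FPKM in deltamethrin replicates 1 and 3, at 0.236 FPKM in the omitted replicate 2 and at up to 1.94 FPKM in controls. The 4 genes ran from 15.4 to 56.4 FPKM in deltamethrin replicate 1 and from 17.7 to 86.7 FPKM in replicate 2. In the omitted replicate 3 they were at 1.06 to 3.10 FPKM, and in controls at no more than 2.26 FPKM. Leaving out any other single library gave 0 genes. Each of the 5 genes thus passed only with the exposed library left out in which its level was lowest. With all 6 libraries, 1 gene also passed in a split that mixed the groups (adjusted p = 0.0437, limma). That split set control replicate 1 and deltamethrin replicates 1 and 3 against the rest. No library was left out of such splits, so how often that step alone brings genes past the threshold is not known. In simulations with 200 changed genes, drawn independently of each other, the test called 66.2% of 4-fold changes, 28.4% of 2-fold changes and 3.48% of 1.5-fold changes. Within those simulations, 1.5-fold and 2-fold changes in few genes were thus mostly not called with 3 libraries per group. The simulations took each gene's estimated spread as its true one, so the shares are a rough guide.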

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

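All 23 alternatives to the main test were compared with its count of 0 genes at an adjusted p under 0.05; voom, the length correction (alone and with the block) and the joint omission of 2 libraries were chosen after seeing the data, as were all repeats of the unadjusted count. The adjusted count stayed at 0 under 20 of them, voom and both scalings included. Among these, the setting that added a 2-fold change to the adjusted threshold of the main test could only give 0. The range over the single libraries left out was 0 to 4: 1 gene without deltamethrin replicate 2 and 4 without deltamethrin replicate 3. An unadjusted p under 0.05 with at least a 2-fold change gave 72 genes in place of the adjusted threshold, and that count became 166 with a pseudocount of 0.1, 180 with 0.01, 137 with voom, 47 with a minimum mean FPKM of 5, 110 without deltamethrin replicate 1 and 163 without deltamethrin replicate 3. The count at an unadjusted p under 0.05 moved from 1103 to 1666 with no filter on low values (37927 genes tested, 5% of them 1896) and to 708 with a minimum mean FPKM of 5 (16071 genes tested, 5% of them 804), in step with the number of genes tested. It stayed within 1.5 times of 1103 under the other 18, and ranged from 869 to 1419 with single libraries left out. At an unadjusted p under 0.05, lower genes outnumbered higher ones under median-of-ratios scaling (542 higher, 586 lower), quantile normalization (532, 576), without deltamethrin replicate 2 (448, 560) and without it and control replicate 3 together (377, 451). The labels do not say that the replicate numbers pair the samples. The fit with the replicate block gave 0 genes at the adjusted threshold and 1114 at the unadjusted one. With the length trend removed as well it gave 0 and 1104. In deviations from the group means, control replicate 1 correlated at 0.07 with deltamethrin replicate 2 and at 0.01 with its own number, both near 0. Control replicate 2 correlated at 0.30 with deltamethrin replicate 1. Control replicate 3 correlated highest with its own number, at 0.23, so pairing is not excluded. The 4 printed genes kept their direction and stayed above the adjusted threshold under the 20 settings tried for each. The difference between within-group and between-group correlations was between -0.00609 and -0.000161 under the 4 alternatives run for it, none of which left out a library. List tests were not run. Counting error of the recovered fragments alone would give a median standard error of 0.08 at 1 to 5 FPKM and 0.03 at 20 to 100 FPKM, against 0.20 and 0.13 observed, so most of the spread in both classes exceeded what depth sets.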

Other observations

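Chosen only after the result was seen were the tests of a shared response, of another tissue, of fragmentation and of depth in the library split, and the split counts at the adjusted and unadjusted thresholds. Genes high in pairs of libraries were also counted. In deltamethrin replicates 1 and 2 together, 9 genes were at 2 FPKM or more and at least 4-fold above the other 4 libraries, and 4 of them at least 8-fold. The 9 genes include the 4 that passed the adjusted threshold without deltamethrin replicate 3, so this count is not separate evidence. The other 14 pairs of libraries had 0 to 4 genes at 4-fold and 0 or 1 at 8-fold. In deltamethrin replicate 1, 11 genes were at least 8-fold below every other library, against 0 to 5 in the others; at 4-fold it was 18 genes there and 18 in control replicate 2, against 1 or 2 in the others.

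The 100 genes that stood far above all other libraries in deltamethrin replicate 2 were weighed first. Depth is argued against, since 101 genes met the same rule after all libraries were thinned to 20284797 fragments, where the highest other library had 7. A response shared by the exposed fish stays open for these genes, since the rule that chose them leaves out genes that were high in other exposed libraries too; the level was above all 3 controls for 23% of the set in deltamethrin replicate 3, where 20.5% is expected with no difference from the controls, and for 51% in deltamethrin replicate 1, where 22.75% is expected. The share lay above the expected one in deltamethrin replicate 1 and near it in deltamethrin replicate 3. With genes chosen by this rule, neither share decides the question. RNA of another tissue or brain region in that library may account for the set and stays open, since no marker can be named. The levels across the set correlated with those of deltamethrin replicate 2 at a rho of 0.597 in deltamethrin replicate 1. The mean rho was 0.423 in controls, with single controls between 0.342 and 0.494. Outside deltamethrin replicate 2 the set lay near the floor, with medians of 0 to 0.18 FPKM. In each of those libraries 23 to 52 of the 100 genes were at 0. These correlations and the shares above thus rest on very low values. A response of single fish to the exposure also stays open and was not tested.

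Control replicate 3 fell with gene length, with a difference of -0.22 on the log2 scale between the longest 20% and the shortest 20% of genes. Abundance differing with length is argued against, since the rank correlation was -0.26 with mean abundance held fixed. Fragmented RNA or the library preparation could give such a trend, and the difference of -0.22 cannot decide it without read positions along genes. The trend does not account for the absence of calls: with length trends removed from every library, 0 genes passed the adjusted threshold, where at least 10 had been set as the mark of that cause.

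The split of control replicates 1 and 2 and deltamethrin replicate 1 from the other 3 libraries gave 2291 genes at an unadjusted p under 0.05, over 1103 for the real groups and 1284 for 5% of the genes. It was singled out as the highest of the 10 splits, which ran from 534 to 2291, and no value is given for how high the highest of 10 would be with no structure among the samples. It sets apart the libraries at the ends of the first principal component, and so is no evidence beyond that component. As the source of this count, length trends are argued against, since the split gave 2352 genes with them removed. The library totals overlapped between the sides, over a range of 0.670 in units of 1000000 fragments. The totals of 1 side lay within the range of the other, so this overlap cannot exclude depth, which stays open. Individual differences between fish, dissection and processing order stay open, and no biological explanation was tested.

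With 0 genes at the adjusted threshold for the real groups, all 10 of the 10 splits necessarily gave as many (highest of the others, 1), which says nothing about chance. At an unadjusted p under 0.05, 6 of the 10 gave at least 1103 genes (highest of the others, 2291), and with a 2-fold change added, 5 of the 10 gave at least 72 genes (highest of the others, 113). With 10 splits no share under 0.05 can be reached.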
